A study of Mus musculus with 2 samples.

How the data were processed

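H3K36me3 was measured by chromatin immunoprecipitation and sequencing in mouse limbs at embryonic day 12.5, in 1 group of 2 biological replicates. Each replicate was a pool of embryos of both sexes, 88 for replicate 1 with 2 technical replicates and 68 for replicate 2 with 1. The authors deposited 4 lists of peaks on the mm10 build: 1 for each replicate, 1 for both replicates pooled, and 1 of replicated peaks, which was found to be an exact subset of the pooled list. Per the labels, the list of replicate 1 was derived from its alignments and 1 further file, and the lists of replicate 2 and of the pool from alignments and 2 further files. What those further files held, the aligner, the peak caller, its threshold and the rule for replicated peaks are not given in the sources used here.

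The per-peak enrichment is a ratio over background computed by the authors, and it was used only to rank or describe peaks within a list. The per-peak significance values are -log10 p and -log10 q as deposited by the authors. Of the peaks, 87.4% in replicate 1 and 94.9% in replicate 2 had a -log10 q of 2 or more. The lists hold no read counts, so the depth per sample is unknown, and no limit based on counts was computed.

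Peaks of a list were merged where they overlapped, and every share is a share of bases covered by the merged peaks. Genes, exons and biotypes came from GENCODE mouse release M21, whose positions are on GRCm38, and gene spans ran from the annotated start to the annotated end of the gene. Genome-wide counts used protein-coding genes of at least 1 kb on chromosomes 1 to 19, X and Y. Gene lists used members of any length. The measure for a gene is the percent of its span covered by peaks. A gene was called marked at 20% or more in both replicates. Errors are standard deviations over the 2 replicates, and no p was computed across genes, because genes are not independent replicates.

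Overlap between replicates was compared with 100 random placements of the peaks within their chromosomes. Each gene list was compared with 10000 random lists of the same size, drawn from 20 classes of gene length. A list was called above or below when the percentile of its median was at least 97.5 or at most 2.5 in both replicates. Chance alone places about 1 list in 20 past those bounds in a given replicate. Exon and intron coverage was compared within marked genes with at least 2 exons. Profiles along the gene used 10 bins in marked genes of at least 5 kb. Domains were replicated peaks joined across gaps of up to 1 kb.

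The 37 gene lists, the tests of the comparisons in the results and the threshold of 20% were chosen before the data were examined, and the exceptions are named as such where they appear. Lists covered limb mesenchyme, Hox clusters, cartilage, bone, tendon, muscle, ectoderm, blood and vessel cells, nerve, other organs, broadly used genes, chromatin regulators, signalling pathways, imprinted genes and 5 gene families. They held 2687 names, of which 2669 were measured, since 16 of the 32 histone names and 2 older names in the H3K36 list have no match in the annotation. The genes named in the text followed a rule fixed with the lists. The rule took 20 set genes, the 2 highest and the lowest member of each list, the 10 most covered genes of at least 20 kb, the 5 genes of at least 5 kb with the largest difference between replicates in each direction, and the genes of the 5 widest domains. Any other gene is said to have been chosen after its values were seen, except where it shares a domain with a named gene.

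Alternatives were peaks with a -log10 q of at least 2, the 93917 best peaks of each replicate by -log10 p, other overlap rules, thresholds of 10% and 40% covered, each replicate left out, the replicated peaks in place of each replicate, genes that overlap no other protein-coding gene, the last 50% of the gene, genes of at least 10 kb, random lists without matching, and other gaps for domains. A pair of alternatives was chosen after seeing the data: rotation of all peaks of a chromosome together, and a list percentile based on the number of marked members. Peaks on scaffolds outside the chromosomes were left out of the comparisons, because the gene measures were defined on chromosomes, and are described in the closing section. The method was tested on simulated data: lists with a shift of 2, 5 and 10 percentage points planted were placed above the bound in 15%, 75% and all of 40 trials, and 7% of 100 lists of long genes without a shift passed a bound. The simulated coverage followed gene length with normal noise, whereas 42.9% of the real genes of at least 1 kb had no covered base. These shares therefore do not give the power for the real lists. Computation used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with Matplotlib 3.10.9.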

Results

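Trimethylation of lysine 36 on histone H3 (H3K36me3), a modification laid down over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in mouse limbs at embryonic day 12.5. At this stage the limb bud holds condensing cartilage, muscle precursors and an overlying ectoderm. The design had 1 group of 2 biological replicates of the B6NCrl strain, each a pool of both sexes. Replicate 1 was made from the limbs of 88 embryos and sequenced as 2 technical replicates, and replicate 2 from the limbs of 68 embryos with 1 technical replicate. No other tissue, stage or mark was part of the series, so the comparisons were between replicates, between regions of the genome and between gene lists fixed before the data were examined. Peak lists carry no read counts, so the sequencing depth of each replicate was unknown and no interval based on reads could be given. All positions are on the mm10 build (GRCm38).

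The mark covered 4.29% of the genome in replicate 1 and 5.90% in replicate 2. Replicate 1 had 193048 peaks over 117 Mb with a median width of 372 bp, and replicate 2 had 187834 peaks over 161 Mb with a median width of 443 bp. Peaks wider than 2 kb held 21.8% of the covered bases in replicate 1 and 40.8% in replicate 2. The authors' enrichment value had a median of 3.17 in replicate 1 and 3.18 in replicate 2, each within its own list.

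The question for the replicates was whether independent pools of limbs gave the same map. Gene coverage was closely related between them: across 21196 protein-coding genes of at least 1 kb, the percent of the gene covered by peaks had a Pearson correlation of 0.980 and a Spearman correlation of 0.971 between replicates. These correlations are across genes, which are not independent replicates. Trrap, a scaffold of histone acetyltransferase complexes, was covered over 91.6% of its span in replicate 1 and 95.4% in replicate 2. Fn1, which encodes fibronectin, had 85.8% and 93.7%, and the albumin gene Alb had no covered base in either. Among genes of at least 5 kb the largest gap lay at Ecm1, an extracellular matrix gene covered over 40.4% in replicate 1 and 84.8% in replicate 2. Ankrd61, Csf1, Naa10 and Abt1 followed with gaps in the same direction. In the opposite direction Evx2, at the edge of the HoxD cluster, had 19.2% in replicate 1 and 4.11% in replicate 2, and Med22, a Mediator subunit gene, had 68.2% and 56.4%. Foxc1, Fuom and Nagpa were also higher in replicate 1.

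**Figure D1:**
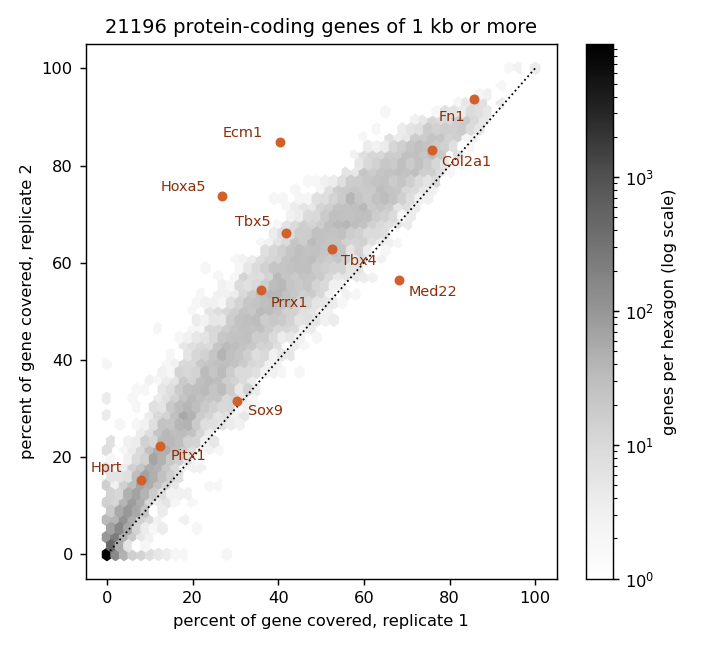
Percent of each protein-coding gene of at least 1 kb covered by H3K36me3 peaks in replicate 1 (x axis) and replicate 2 (y axis); grey hexagons show the number of genes on a log scale, the dotted line marks equal coverage and orange points are named genes. Most covered genes lie above the line, and among genes marked in both replicates 96.7% were higher in replicate 2.

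Of the peaks of replicate 1, 81.3% had more than 50% of their length covered by peaks of replicate 2, against a mean of 6.22% for 100 random placements within chromosomes. Of the peaks of replicate 2, 48.6% were covered by replicate 1 in the same way, against 4.04% at random. The bases covered in both replicates came to 103 Mb, which was 87.9% of the bases of replicate 1 and 64.0% of those of replicate 2. The Jaccard index of covered bases was 0.588, against a random mean of 0.0294. Peaks that touched no peak of the other replicate were narrower and less enriched than shared peaks within the same list. In replicate 2 the 68540 such peaks had a median width of 280 bp and a median enrichment of 2.75, against 719 bp and 3.91 for its shared peaks. In replicate 1 the 25443 such peaks had medians of 230 bp and 2.64, against 430 bp and 3.35. The share of peaks called common was 32.9% of replicate 1 and 33.8% of replicate 2 when 50% of both peaks had to overlap.

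The authors' replicated set held 120814 peaks over 154 Mb, with a median width of 730 bp. It kept 65.7% of the peaks of the pooled list and 89.5% of its bases, and the pooled peaks left out had a median width of 254 bp. Of the replicated peaks, 86.6% overlapped peaks of both replicates by at least 1 bp and 68.2% were covered over more than 50% of their length in both.

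Protein-coding genes held nearly all of the mark. They contained 94.3% ± 0.197 of the covered bases (SD, n = 2), while they make up 38.2% of the genome and received 40.9% and 40.8% of randomly placed peak bases. Exons and untranslated regions took 17.0% of covered bases in replicate 1 and 15.3% in replicate 2, and introns took 77.5% and 78.9%. The 10 kb downstream of genes held 3.37% and 3.57%, against 0.215% and 0.217% in the 10 kb upstream. Long non-coding genes outside these regions held 0.415% and 0.464%, although they span 4.87% of the genome.

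A gene was called marked when at least 20% of its span was covered in both replicates. Marked genes numbered 6913, or 32.6% of the 21196 genes, and 9088 genes (42.9%) had no covered base in either replicate. Replicate 1 alone marked 26 further genes and replicate 2 alone 1226. Among marked genes the median coverage was 46.9% in replicate 1 and 60.5% in replicate 2. Of genes of at least 20 kb, Trrap had the highest coverage, 93.5% ± 2.67 (SD, n = 2; chromosome 5, 144767732 to 144859778). Prr12 followed with 92.4% ± 0.318 and Ints1, a subunit of the Integrator complex, with 92.3% ± 1.06. The splicing factor gene Sf3a1, the RNA exosome gene Exosc10 and the H3K36 demethylase gene Kdm4a each lay between 91.2% and 91.4%. Kpnb1, Sec24c, Ddb1 and the condensin gene Ncapd2 completed the 10 highest, between 90.4% and 90.7%. The count of marked genes was 4319 with a threshold of 40% covered.

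Joining replicated peaks across gaps of up to 1 kb gave 39748 domains, of which 5048 were 10 kb or wider. The widest, 114.7 kb on chromosome 4 from 32662720 to 32777375, lay over Mdn1, a ribosome assembly gene. Domains of 113.4 kb over Wdfy3, 108.2 kb over Smarcc1, 106.2 kb over Hectd4 and Trafd1 and 106.1 kb over Zfp532 came next. The widest domain and its genes depended on the gaps joined: it was 202.9 kb over Fbn2 with gaps of up to 3 kb and 45.0 kb over Ubr4 with none, and none of the 5 widest was over the same gene. Of the domains of 10 kb or more, 99.6% touched a protein-coding gene.

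Within marked genes the mark was low at the start and high toward the end. In the 6237 marked genes of at least 5 kb, mean coverage was 7.17% in the opening bin of 10 equal bins in replicate 1 and 10.5% in replicate 2, and it reached 66.6% and 79.6% in the ninth bin. The last 25% of the gene exceeded the opening 25% by a median of 50.5 ± 4.45 percentage points (SD, n = 2), and it was the higher in 91.3% of genes in replicate 1 and 92.3% in replicate 2. The first 1 kb had no covered base in 96.8% of these genes in each replicate. Exons were covered more than introns of the same gene, by a median of 14.8 ± 1.83 points (SD, n = 2) over 6800 genes with at least 2 exons. Exonic coverage was the higher in 77.8% of genes in replicate 1 and 75.1% in replicate 2. First exons had a median coverage of 0, whereas last exons had 72.1% and 88.6%. Exons and introns were not compared at equal positions along the gene, so the exon excess was not separated from the rise toward the end.

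**Figure D2:**
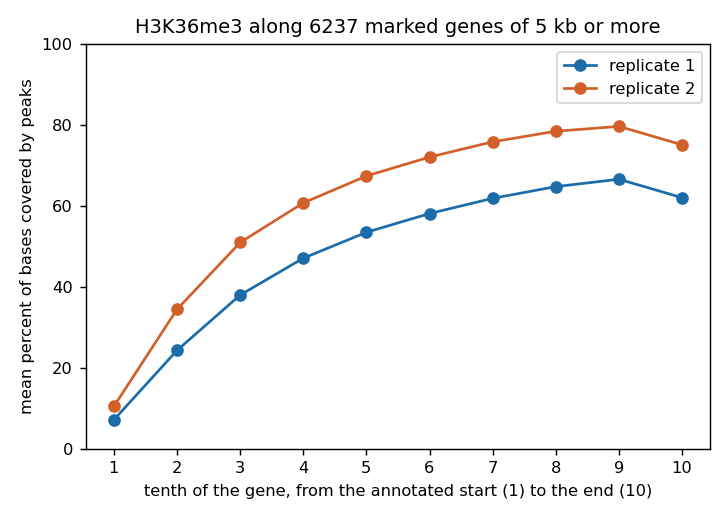
Mean percent of bases covered by H3K36me3 peaks (y axis) in 10 equal bins from the annotated start to the end of 6237 marked genes of at least 5 kb (x axis), 1 line per replicate. Coverage rises from 7.17% to 66.6% in replicate 1 and from 10.5% to 79.6% in replicate 2 by bin 9, and is 62.0% and 75.1% in bin 10.

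Gene length went with coverage. The share of genes marked in both replicates was 19.8% for genes of 1 to 5 kb, 36.7% for 5 to 20 kb, 41.0% for 20 to 100 kb, and lowest above 100 kb, where 299 of 2490 genes were marked. Gene lists were therefore compared with random lists matched on length.

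Genes on the X chromosome carried the mark less often than autosomal genes. Of 877 X-linked genes, 9.01% were marked in replicate 1 and 14.3% in replicate 2, against 34.0% and 39.8% of 20156 autosomal genes. The difference was -25.3 ± 0.340 percentage points (SD, n = 2), far beyond the spread between replicates. Every autosome had between 25.4% (chromosome 14) and 42.7% (chromosome 8) of its genes marked in both replicates, while the X had 8.89% and none of the 163 genes of the Y was marked. Among marked genes the X-linked ones were also less covered, with a median of 29.0% against 47.0% in replicate 1 and 38.9% against 56.0% in replicate 2. The lowest members of the housekeeping, DNA replication and respiratory chain lists were X-linked: Hprt, of purine salvage, had 11.7% ± 5.21, Pola1, the DNA polymerase alpha subunit gene, 3.12% ± 1.02, and Ndufa1, of respiratory complex I, 3.15% ± 4.45 (SD, n = 2). Of the 7 X-linked members of the broadly used and chromatin lists 3 were marked in both replicates, and these were named after their values were seen: Pgk1, a glycolytic gene, the ribosomal protein gene Rps4x (42.2% ± 18.1) and Rbbp7 (32.1% ± 13.9).

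Genes that most cells use were marked nearly throughout. The DNA replication and cell cycle list had 38 of 39 members marked and a median coverage of 71.8% ± 7.63 (SD, n = 2), with Mcm2 at 89.3% ± 4.11 and Mcm5 at 88.7% ± 4.81, both subunits of the replicative helicase. The splicing list had 35 of 36 members marked (median 70.3% ± 5.07), led by Sf3a1 and Sf3b3, and its exception was Srsf10. Ribosomal protein genes had 46 of 50 marked (median 63.0% ± 5.30), with Rps3 at 80.5% ± 4.61 and Rps19 at 78.0% ± 1.13. The lowest, Rps14, had 7.26% over an annotated span of 31.4 kb that overlaps another protein-coding gene. The housekeeping list had 29 of 32 marked (median 56.7% ± 9.64), including Actb at 63.0% ± 4.57 and Gapdh at 44.1% ± 7.23, and the respiratory chain list had 29 of 34 (median 56.8% ± 10.8), led by Uqcrc1 and Atp5b. Each of these 5 lists lay at percentile 100 of 10000 length-matched random lists in both replicates.

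Most genes of the chromatin lists were marked. Of the measured writers, erasers and readers of H3K36 methylation, 21 of 25 were marked, with a median of 62.5% ± 8.74 (SD, n = 2). Kdm4a had 91.2% ± 2.86 and Supt6, a histone chaperone that travels with RNA polymerase II, 78.4% ± 1.94, while Phf19 had no covered base. In the Polycomb and Trithorax list 21 of 29 were marked (median 56.1% ± 11.3), with Kmt2b at 90.1% ± 0.505 and Kmt2d at 86.4% ± 1.83, both H3K4 methyltransferases, and Cbx7 at 0.701% ± 0.992. Both lists lay at percentile 100 in both replicates.

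**Figure D3:**
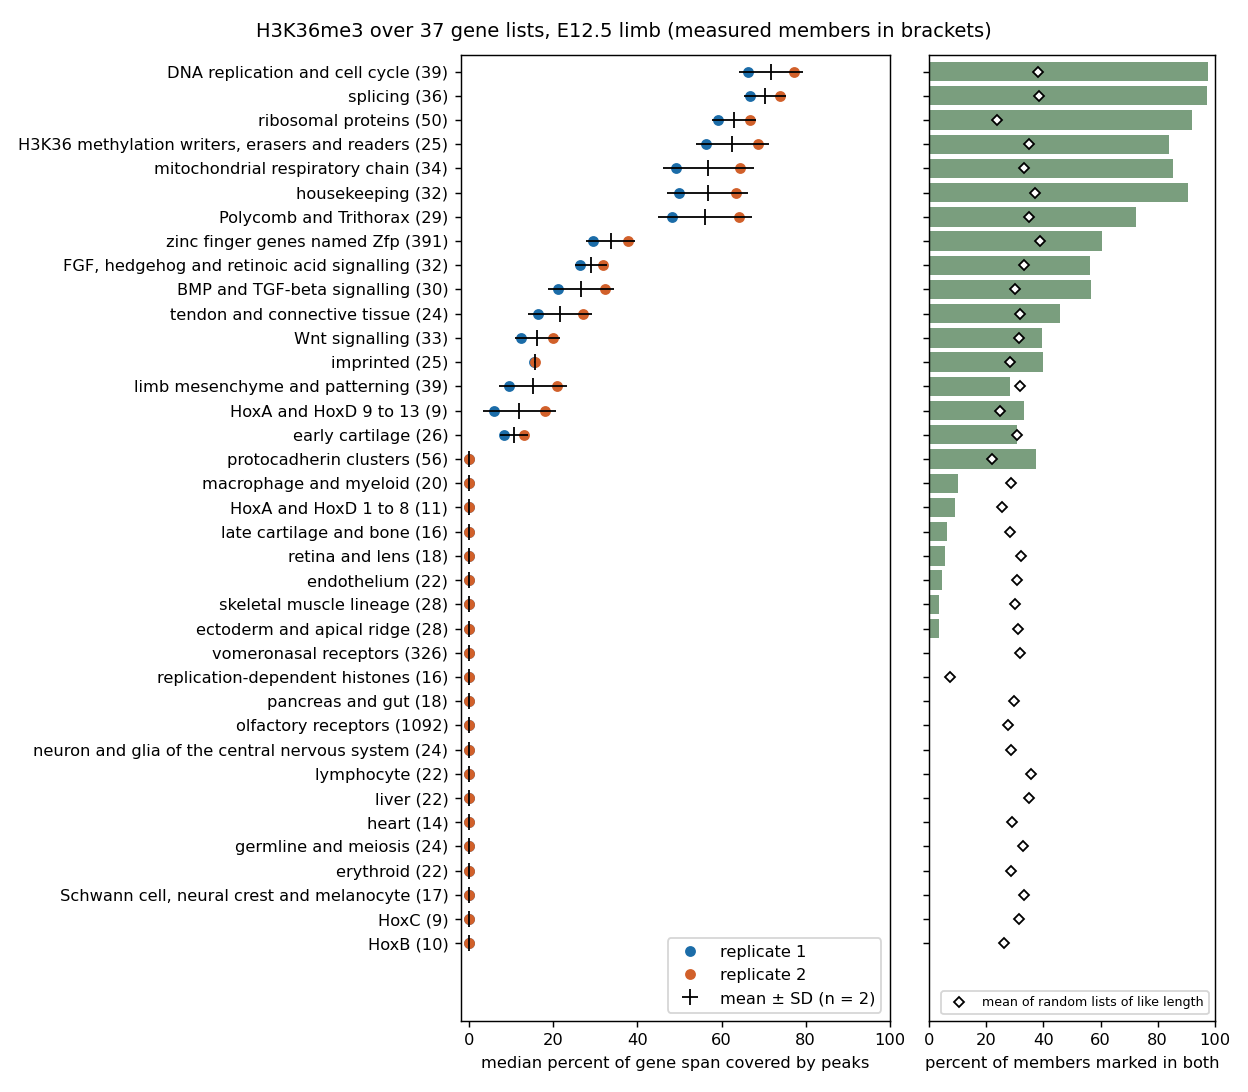
Left, median percent of the gene span covered by H3K36me3 peaks for 37 gene lists, per replicate and as the mean ± SD of 2 replicates; right, percent of each list's measured members marked in both replicates (bars) and the mean of length-matched random lists (diamonds). The DNA replication and cell cycle list is highest at 71.8%, and 21 lists have a median of 0.

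Of 39 genes in the limb mesenchyme and patterning list 11 were marked and 4 had no covered base in either replicate, and the list's median of 15.2% ± 8.05 (SD, n = 2) lay at percentiles 89.5 and 95.1, inside the range of random lists. By the number of marked members, chosen after the data were seen, the list lay at percentile 31.3, with a mean of 12.4 marked in random lists. The forelimb gene Tbx5 had 53.9% ± 17.2 (chromosome 5, 119832668 to 119885219) and the hindlimb gene Tbx4 had 57.7% ± 7.29 (chromosome 11, 85886422 to 85916097). Prrx1, a marker of limb mesenchyme, had 45.2% ± 12.9. The hedgehog targets Gli1 and Ptch1 had 61.1% ± 9.35 and 59.4% ± 7.02, although Gli1 overlaps another protein-coding gene, while Gli3 had 17.6% ± 5.94 over 266.8 kb. Hand2 had 18.5% in replicate 1 and 29.9% in replicate 2, and so passed 20% in replicate 2 only, and the hindlimb gene Pitx1 had 17.3% ± 7.10. Shh, which is made in a small posterior zone, had no covered base in either replicate, nor had Zic3, and Fgf10 had 0.373% ± 0.017.

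In HoxA and HoxD 9 to 13, the genes that pattern the limb from the shoulder outward, 3 of 9 were marked: Hoxd10 with 43.4% ± 2.98, Hoxa10 with 40.7% ± 8.57 (SD, n = 2) and Hoxa9, which was named after its values were seen and shares a domain with Hoxa10. The digit genes Hoxa13 and Hoxd13 had 12.3% ± 8.10 and 9.36% ± 5.07, Hoxd9 had 0% in replicate 1 and 2.38% in replicate 2, and Hoxd12 had none. In the replicated peaks Hoxa13 kept 10.1%, while Hoxd13 and Hoxd9 had no covered base. In HoxA and HoxD 1 to 8 only Hoxa5 of 11 genes was marked, with 26.9% in replicate 1 and 73.7% in replicate 2, in a domain of 6.8 kb that also touches Hoxa3, Hoxa6 and Gm28308. No gene of HoxB (10 genes) or HoxC (9 genes) was marked, and Hoxc10, Hoxc5 and Hoxc4 had no covered base. The median of HoxA and HoxD 9 to 13 lay at percentiles 87.7 and 92.0 of random lists, short of the bound. The medians of the other 3 lists were 0, so their percentiles could not fall below the bound. By the number of marked members, chosen after the data were seen, HoxB lay at 2.41 and HoxC at 1.41. HoxA and HoxD 1 to 8 lay at 10.3 and HoxA and HoxD 9 to 13 at 72.8, both within chance. Random lists drew genes singly, whereas Hox genes are neighbours, so the values of HoxB and HoxC can overstate a departure from chance.

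**Figure D4:**
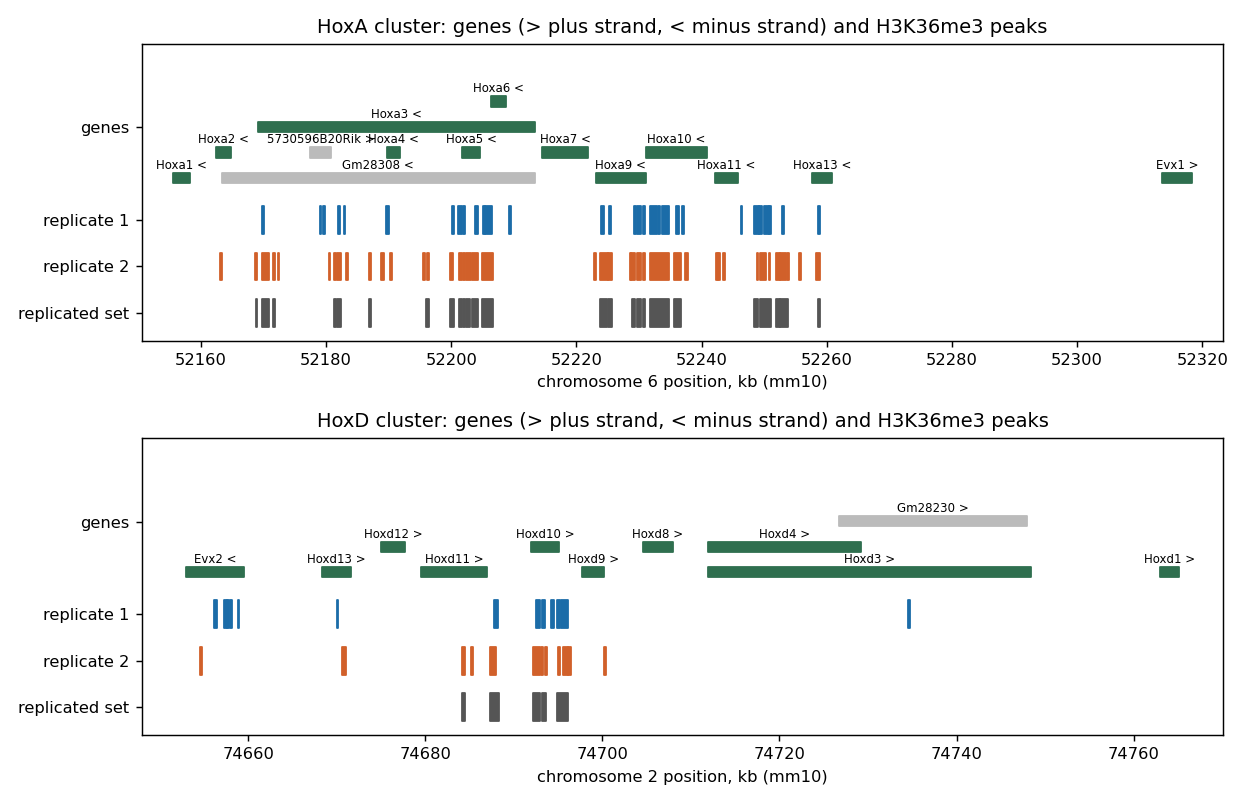
Genes and H3K36me3 peaks of replicate 1, replicate 2 and the replicated set over the HoxA cluster (chromosome 6, 52150590 to 52323378) and the HoxD cluster (chromosome 2, 74647991 to 74770142); the x axes give position in kb on mm10 and arrows give the strand. Peaks cover 13.5 kb of the HoxA window in replicate 1 and 23.1 kb in replicate 2, and 4.41 kb and 4.47 kb of the HoxD window.

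Genes of cartilage and connective tissue matrix included some of the most covered tissue genes, whereas bone genes were mostly bare. In the early cartilage list 8 of 26 genes were marked, with Col2a1, the major cartilage collagen, at 79.6% ± 5.10 (chromosome 15, 97975602 to 98004695), Fgfr3 at 54.9% ± 7.88 and the chondrogenic regulator Sox9 at 31.0% ± 0.881 (SD, n = 2). Matn3 had no covered base. In the tendon and connective tissue list 11 of 24 were marked, led by Fn1 with 89.8% ± 5.56 and Pdgfra with 82.9% ± 1.72, while Thbs4 had none. Of the late cartilage and bone list only Ifitm5 of 16 genes was marked, with 85.9% ± 14.2, in a domain that also covers Pgghg and Gm45717. Phex had no covered base and the osteoclast gene Ctsk 13.6% ± 0.539. The medians lay at percentiles 87.2 and 86.0 for early cartilage, and 94.8 and 95.5 for tendon, short of the bound. The median of late cartilage and bone was 0, which could not fall below it. The percentile by the number of marked members, chosen after the data were seen, was 1.53 for that list. It was 50.9 for early cartilage and 93.3 for tendon, both within chance.

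Few genes or none were marked in the lists of skeletal muscle, ectoderm, endothelium, macrophages, erythroid cells, and Schwann cells, neural crest and melanocytes. The share of these cells in the limbs was not measured. The skeletal muscle list had 1 of 28 members marked, Six4 with 54.9% ± 10.1, and Myod1 and Pax3 had no covered base. The ectoderm and apical ridge list had 1 of 28, Bmp2 with 31.1% ± 14.2 (SD, n = 2), and the epidermal regulator Trp63 had none. The endothelium list had 1 of 22, Fli1 with 43.3% ± 10.4, and the receptor gene Flt1 had none. The macrophage list had 2 of 20, Cd68 with 97.8% ± 3.13 and Fcer1g with 27.2% ± 3.17. The domain over Cd68 also covers Eif4a1, and that over Fcer1g also covers Ndufs2. The erythroid list (22 genes, including Hba-a1 and Ank1) and the Schwann cell, neural crest and melanocyte list (17 genes, including Cdh19) had no marked member.

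Lists of other organs held almost no marked gene. No member was marked in the lists of liver (22 genes), heart (14), pancreas and gut (18), central nervous system (24), lymphocyte (22) and germline (24). Alb and Cps1 of liver, Actn2 of heart, Sis of gut, Dlg2 of neurons, Il2ra of lymphocytes and Sycp1 of meiosis had no covered base in either replicate. The retina and lens list had 1 of 18 marked, Rom1 with 30.5% ± 7.84 (SD, n = 2), in a domain shared with B3gat3. The olfactory receptor genes had no covered base in any of 1092 members, and none of 326 vomeronasal receptor genes was marked. A median of 0 ties with the many random lists whose median is also 0, so the planned percentile could not place these lists below its bound. By the number of marked members, an alternative chosen after the data were seen, 17 lists lay below percentile 2.5, among them skeletal muscle (0.025), endothelium (0.15) and liver (0).

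The BMP and TGF-beta list had 17 of 30 members marked and a median of 26.6% ± 7.83 (SD, n = 2), at percentiles 99.5 and 99.5, with Tgfb3 at 60.6% ± 6.66, Gdf11 at 60.1% ± 8.47 and Tgfb1 bare. The FGF, hedgehog and retinoic acid list had 18 of 32 marked and a median of 29.0% ± 3.81, at percentiles 99.6 and 98.2, led by the ciliary hedgehog regulator Kif7 (70.1% ± 9.83) and the retinoid receptor gene Rxrb (64.1% ± 8.08), with Fgf7 bare. The Wnt list had 13 of 33 marked, led by the signal transducers Dvl3 (76.1% ± 7.23) and Dvl2 (70.1% ± 1.90), and its median of 16.1% ± 5.36 lay at percentiles 91.3 and 90.4, short of the bound. The difference between the pathway lists was not tested.

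Of 391 zinc finger genes named Zfp, 237 were marked and the median was 33.6% ± 5.82 (SD, n = 2), at percentile 100 in both replicates, with Zfp869 at 97.8% ± 3.09 and Zfp335 at 88.4% ± 0.125. In the protocadherin clusters 21 of 56 genes were marked, all of them overlapping another gene, with Pcdhgc5 at 59.3% ± 10.8, Pcdhgc4 at 59.0% ± 7.89 and Pcdha1 bare. None of the 16 replication-dependent histone genes measured, such as Hist1h1d and Hist1h1e, had a covered base. Their median length was only 0.69 kb, and random lists of like length had a mean of 1.20 marked members. By the number of marked members the histone list lay at percentile 13.4, within chance. Of 25 imprinted genes 10 were marked, with Nnat, which overlaps another gene, at 81.6% ± 4.28 and Igf2r at 69.7% ± 13.1, and Rasgrf1 was bare. The imprinted list's percentiles of 97.4 and 91.0 did not reach the bound in both replicates, and in all 10 of the 37 lists stood above random lists. The lists share genes and were not corrected for their number. Of protein-coding genes, 21.5% overlap another, so that peaks without strand cannot be assigned between them. Kif7, Tgfb3, Dvl2, Supt6, Gapdh, Sf3b3, Zfp335 and Ddb1 are among the overlapping genes named above. Random lists drew genes singly, so percentiles of families that lie in clusters can overstate a departure from chance.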

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

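The tests of the gene content of the X were chosen only after the result was seen; the other tests below were chosen before, that of enrichment on the X when the lower coverage of marked X-linked genes was already known. Signal in data that the comparisons did not use drew attention to 4 values. Peaks on scaffolds outside the assembled chromosomes numbered 25 in replicate 1 and 23 in replicate 2, and 2 of the 77 protein-coding genes annotated on scaffolds were marked. Long non-coding genes of at least 1 kb that lie 5 kb or more from any protein-coding gene were marked in 24 of 4538 cases. Domains of 10 kb or more that touch no protein-coding gene numbered 19.

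X-linked genes were marked less often than autosomal genes. A different gene content of the X, with fewer broadly used genes, could be weighed only on 7 X-linked members of the broadly used and chromatin lists. They had a median coverage of 11.7% (8.02% in replicate 1 and 15.4% in replicate 2), below the lower quartiles of 42.8% and 53.1% of 236 autosomal members. Of the 7, 3 were marked, against 215 and 223 autosomal members. The low values of 3 others had been seen before, so the median of all 7 partly restates them. The remaining 4 had medians of 25.9% and 48.5%, at percentiles 0.77 and 4.64 of the medians of random sets of autosomal members of like length. For these 4 genes the values argue against gene content as the whole cause, less strongly in replicate 2. Weaker enrichment over the X may contribute: in 78 marked X-linked genes the highest peak enrichment had a median of 4.46 (4.23 and 4.70), below the autosomal lower quartiles of 4.93 and 5.66. Copy number of the X in pools of both sexes, X inactivation and the authors' peak threshold all stay open, as none of these was tested.

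Replicate 2 covered more of the genome than replicate 1. Of the 1226 genes marked in replicate 2 alone, 2.45% (30 genes) had no covered base in replicate 1. The 1226 genes had a median coverage of 15.8% in replicate 1 and 26.5% in replicate 2. They were selected for lying on opposite sides of the threshold for a marked gene, which favours genes near it. The share and the medians therefore cannot tell genes marked in only 1 pool of embryos from weaker detection in replicate 1. With 93917 best peaks in each replicate, the covered bases were 84.4 Mb and 127 Mb. Sequencing depth, the different further files behind each list and differences between the pools, graded or not, stay open.

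Zinc finger genes were frequent among the strongest peaks: 41 of the best 100 peaks of replicate 1 and 45 of those of replicate 2 overlapped a Zfp gene, as did 11.7% and 12.2% of the best 1000, against 1.95% and 1.86% of all peaks. Long last exons are argued against as the whole cause, since other marked genes with a last exon as long as the Zfp median of 2.56 kb passed the 95th percentile of other marked genes' highest enrichment in 5.75%, against 24.5% and 29.1% of Zfp genes. Zfp genes with no other Zfp gene within 500 kb passed it in 16.2%, between the bounds set in advance, so tandem copies could account for part of the pattern or for none. The reads behind shared sequence were not analysed here, and no biological explanation was tested.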

How the results depend on the processing

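The percentile by marked members and the rotation of peaks were chosen only after the data were seen, and the cause of each shift below was not tested. Under any overlap of 1 bp, 86.8% of replicate 1 and 63.5% of replicate 2 peaks were shared, and with 50% of both peaks 32.9% and 33.8%. With a -log10 q of at least 2 the shares were 84.0% and 46.3%, the Jaccard index 0.581, the Pearson correlation 0.975, the Spearman correlation 0.970 and the X difference -24.9 points. With equal numbers of peaks the share of replicate 1 was 86.2%, the Jaccard index 0.572, the correlations 0.960 (Pearson) and 0.960 (Spearman), and the share of bases in protein-coding genes 95.03%. Genes of at least 10 kb gave correlations of 0.984 and 0.982. At 40% covered, 4319 genes were marked, the exon excess was 10.8 points and the X difference -21.0 points. At 10% covered, 8453 genes were marked, the exon excess was 16.7 points and the X difference -24.7 points. The X difference was -26.0 points with the replicated peaks and -21.5 points for genes that overlap no other. Domains joined over 3 kb numbered 22313 with a widest of 202.9 kb, and without joining 120814 with a widest of 45.0 kb.

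Leaving out a replicate gave 6939 to 8139 marked genes, 94.2% to 94.5% of bases in protein-coding genes, an exon excess of 15.5 to 16.1 points, a 3 prime excess of 47.3 to 51.1 points and an X difference of -25.5 to -25.0 points. Every one of the 37 lists kept its side of the bounds under the alternatives chosen before the data were seen, except the olfactory receptors against unmatched lists (percentile 1.03) and the protocadherins among genes that overlap no other, where no member was left. By the number of marked members, 19 lists kept their side and 18 passed a bound that their median had not passed. These were lymphocyte, central nervous system, liver, germline, olfactory and vomeronasal receptors (percentile 0), erythroid (0.01), skeletal muscle and ectoderm (0.025), Schwann cell (0.05), pancreas and gut (0.06), endothelium (0.15), heart (0.315), retina and lens (0.44), HoxC (1.41), late cartilage and bone (1.53), HoxB (2.41) and, above, protocadherins (99.7). Random lists drew genes singly, whereas Hox, receptor and protocadherin genes lie in clusters, and all 21 marked protocadherins overlap another gene. Percentiles of such lists can overstate a departure from chance. The number of marked members moved in 10 lists at 10% covered and in 14 at 40%. Of 141 named genes, the coverage of 71 moved by more than the spread between replicates in the last 50% of the gene, 37 with equal numbers of peaks, 25 with the replicated peaks and 4 with a -log10 q of at least 2. With the replicated peaks Hoxd13 and Evx2 had no covered base, nor had other named genes with low coverage, among them Ndufa1, Fuom, Cbx7, Hoxd9 and Fgf10. Unknown depth limits every statement that a gene had no covered base. No paired analysis was possible because the design has 1 group.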

Other observations

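The genes in this part were chosen after their values were seen, and no test was run on them. Some long non-coding genes were heavily covered. The imprinted Dlk1 to Dio3 region of chromosome 12 held Meg3 with 61.4% ± 16.7, Rian with 29.9% ± 10.1 and Mirg with 66.4% ± 14.2 (SD, n = 2). A domain from 109709832 to 109749844 ran over Mirg and its microRNA genes. Mir17hg, host of a microRNA cluster that acts in growth, had 87.1% ± 15.9, and the snoRNA hosts Snhg17 and Snhg20 had 77.8% ± 4.75 and 36.2% ± 9.07. Malat1, an abundant nuclear RNA, had 54.8% ± 8.20, whereas its neighbour Neat1 had 0.522% ± 0.739. Lncppara, which carries let-7 microRNAs, had 33.1% ± 3.69. H19 had 0% in replicate 1 and 41.7% in replicate 2. The Hox transcripts Hotair, Hottip and Hotairm1 had no covered base in either replicate.

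On the X, the non-coding Ftx had 28.7% ± 12.4, with a domain of 25.3 kb, while Xist, the RNA that coats the inactive X, had 2.05% ± 0.151 (SD, n = 2). Among X-linked members of the broadly used and chromatin lists, Pgk1 had 31.0% in replicate 1 and 56.4% in replicate 2, Rps4x 42.2% ± 18.1, Rbbp7 32.1% ± 13.9 and Kdm6a 7.96% ± 3.02. A peak over Mid1, near the end of the X, was among the 20 best of both replicates by -log10 p. Its width was 1.11 kb in replicate 1 and 1.12 kb in replicate 2, and its enrichment was 7.74 and 9.19. The best peak of replicate 1 lay over Zfp810 on chromosome 9 from 22276316 to 22281184 with an enrichment of 17.1, and Zfp68, Zfp37 and Spred2 were also among the 20 best of both replicates. On an unlocalised scaffold of chromosome 4 a protein-coding gene was covered over 27.1% ± 0.150, with a peak of 5.53 kb and an enrichment of 13.2 in replicate 1.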
